A study of Homo sapiens with 6 samples.

How the data were processed

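The libraries measured total RNA of DU 145 cells, an established human castration-resistant prostate cancer line, after 48 h with talazoparib, an inhibitor of the PARP1 and PARP2 enzymes, or in a control group. Each group had 3 libraries, numbered 1 to 3 in the labels. The control label reads "DMOS", which was taken as a misspelling of the solvent DMSO. The series design names doses of 5, 10 and 20 µM, and the labels of these libraries do not say which was used for sequencing. PC-3, the other line in the design, was not analysed here. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

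Per the labels' protocols, RNA was extracted with TRIzol, its integrity was assessed on a Bioanalyzer, and libraries were made with the VAHTS Universal V6 RNA-seq kit. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks, HTSeq and the GRCh38 build. Versions, the gene annotation and the strand setting are not given in the sources used here. The deposited count table held whole-number counts for 24305 gene symbols, with totals of 39123997 to 39585727 per library. The FPKM table deposited by the authors held the same genes: each FPKM equalled the count divided by a gene length and by the column total of the count table. The lengths this implies were whole numbers within 0.01 nt for 99.95% of the 21065 genes with a count, so the FPKM values hold no measurement beyond the counts, and the lengths were taken from them. These deposited gene lengths are called mRNA lengths below, though not every one can be. DICER1 has 19981 nt against 12294 exon bases in GENCODE, and CHAC1 has 6081 nt against a genomic span of 3042 bp.

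Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, libraries were scaled by TMM, and talazoparib was compared with control by edgeR's quasi-likelihood test with robust dispersion and Benjamini-Hochberg adjustment at 0.05. CPM values are counts scaled to the TMM-adjusted library sizes, except that levels of untested genes and of 3 counts use the total counts. Errors are SD over 3 libraries, or SE for log2 fold changes. That SE is the absolute log2 fold change divided by the square root of the test's F statistic. A set of 26 gene lists, fixed before the data were examined, was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. That last form takes its degrees of freedom from the 6 libraries and not from the genes, so it has little power here. Members past the gene test were counted over all genes tested and adjusted over the list alone. The self-test used simulated counts for this comparison with known changes in a small part of the 14299 genes tested: the test recovered 51.0% of genes changed 1.5-fold, 75.5% at 2-fold, 93.6% at 3-fold and 100% at 4-fold, with 11 unchanged genes called. Of 10 simulated lists, camera recovered 5 of 5 changed lists and called none of the other 5. Those lists held random genes simulated independently and without a GC or length trend. They cannot show how often camera falsely calls lists whose genes are correlated or share that trend.

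The named genes follow a rule set before the data were examined: the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean CPM of at least 5 and no overlap between the groups; PARP1 and PARP2; CTNNA1, as a check on the cell line; and up to 4 members of each list with the smallest adjusted p, with any member named where it was not measured. Some genes that the rule names are not reported here. Genes named for other reasons are said to be chosen after their values were seen. DESeq2 1.42.0 and limma-voom, other scalings and filters, a fold threshold, FPKM-based limma fits, the replicate number as a block and the removal of each library were tried as alternatives set before the data were examined.

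GC content of the longest transcript (protein-coding where there was one) in GENCODE release 29 and the deposited lengths were available for 13717 of the 14452 genes tested (94.9%), and for none of the mitochondrially encoded genes. After the data were examined, further fits removed the trend of each library's log2 CPM deviation from the gene's mean over GC content and log2 length, fitted with natural splines of 5 degrees of freedom, as an offset in the same edgeR test; values from these are called trend-removed. Simulated data were given the libraries' own trends. Of genes unchanged but for that trend, the test without this offset called 6198 of 14296 tested, and the test with it 8 of 13601. The same spline form made and removed the trend, so this shows only that the offset removes what it models. It cannot show that the offset suits the real libraries or spares a response to the drug.

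Coordinates are 1-based positions from RefSeq's GRCh38.p14 gene table. HLA genes, histone and ribosomal protein genes, ALPG, RAET1E and RAET1G, and the mitochondrially encoded genes have near-identical copies elsewhere, and their values are uncertain where reads could be split. In GENCODE, another gene covers over 20% of the exon bases of ZBED6, XRCC3, ICAM1, PSMB8, DDIT4, CTSD, IER3, CD68 and RAET1E, so their counts may include or lack reads shared with it. ZBED6 shares 96.0% of its exon bases with ZC3H11A. Figures were drawn with matplotlib 3.10.9.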

Results

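RNA of DU 145 prostate cancer cells was sequenced after 48 h with talazoparib (n = 3 libraries) and in a control group (n = 3). The series design describes DU 145 as a model deficient in homologous recombination repair and asks how the drug changes its transcriptome. Total counts ran from 39123997 to 39585727 per library, and 18027 to 18344 genes had at least 1 count in a library.

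With talazoparib, 10 of 17 NF-kB targets and cytokines rose and 3 fell, and 13 of 17 MHC class I antigen presentation genes rose and 1 fell (camera adjusted p = 0.00665 and 0.00209; 0.50 for both with an estimated correlation). In the GC decile that holds the MHC class I list's median GC content (52.64% to 55.88%), 41.3% of all genes rose and 7.87% fell. ICAM1, an adhesion molecule induced by NF-kB, rose from 64.6 ± 2.88 to 152 ± 6.68 CPM (SD, n = 3 each), and CXCL8, a neutrophil chemokine, from 24.6 ± 1.24 to 67.2 ± 11.6 CPM. The immunoproteasome subunit PSMB8 rose from 9.01 ± 0.158 to 21.4 ± 1.34 CPM. Of 24 homologous recombination and Fanconi anaemia genes 16 fell and 3 rose, and of 24 mitosis genes 15 fell and 3 rose (camera adjusted p = 0.00485 and 0.0114; 0.50 for both with an estimated correlation). With the GC and length trend removed their median log2 fold changes went from -0.84 to -0.30 and from -0.47 to -0.21, and with GC alone removed the mitosis list did not pass (camera adjusted p = 0.326). In the GC decile that holds the median GC content of both lists (41.46% to 43.87%), 61.7% of all genes fell and 4.15% rose. BRCA2, which acts in strand exchange at resected DNA, fell from 8.82 ± 2.01 to 1.79 ± 0.415 CPM, and the mitotic kinesin CENPE from 12.4 ± 0.324 to 2.95 ± 0.837 CPM; their log2 fold changes went from -2.30 to -1.29 and from -2.07 to -1.20 trend-removed. Of 14452 genes tested, 8200 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3873 of them higher and 4327 lower. Changes of at least 2-fold numbered 398 upward and 1409 downward, and with the GC and length trend of the mRNAs removed 280 upward and 255 downward. The groups did not overlap for 9302 of the tested genes (64.4%, against 10% by chance).

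Changes followed the composition of the mRNA. In the decile of genes with the lowest GC content the median log2 fold change was -0.73, and in the highest it was 0.43. Over deciles of deposited length the median went from 0.35 in the shortest to -0.65 in the longest. Control replicate 1 differed from control replicates 2 and 3 along the same axes, by a median of -0.22 to 0.18 over the GC deciles. With the GC and length trend removed, a correction chosen after the data were examined, 6063 of 13717 genes changed (3014 higher, 3049 lower); 3592 were called in the same direction in both fits, and 539 were called in opposite directions. In the paragraphs on gene groups, the number after a slash is the gene's trend-removed log2 fold change.

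**Figure D1:**
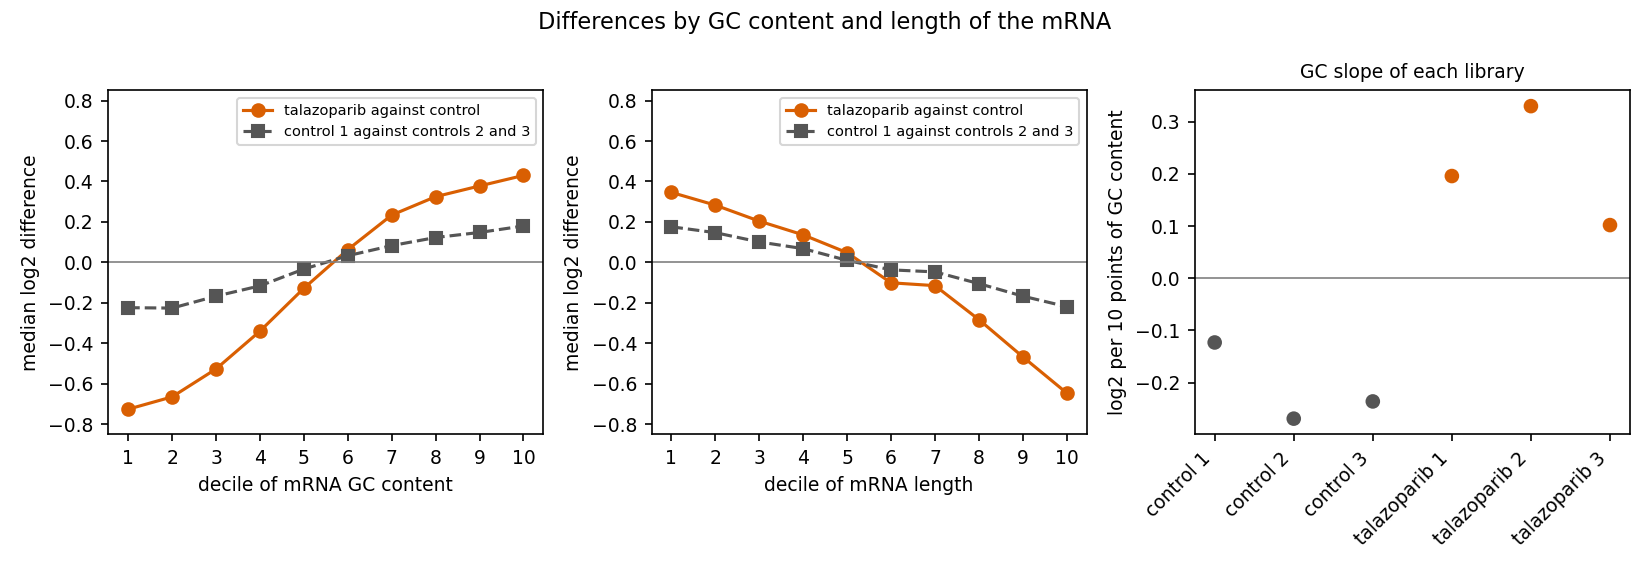
Left and middle: median log2 difference per decile of mRNA GC content and of mRNA length, for talazoparib against control (circles) and for control replicate 1 against control replicates 2 and 3 (squares), over 13717 genes. Right: slope of each library's log2 CPM deviation on GC content; the 3 control libraries lie between -0.27 and -0.12 per 10 points of GC and the 3 talazoparib libraries between 0.10 and 0.33.

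Among genes passing the naming rule, the largest rises were in C11orf86 (log2 fold change 2.74 ± 0.16, SE; chromosome 11, 66975304 to 66977009) and MB, which encodes the oxygen-binding protein myoglobin (2.51 ± 0.17; chromosome 22, 35606764 to 35623354). Rises of 1.67 to 1.93 were found for the synaptotagmin SYT12, the BH3-only apoptosis gene BMF, the proline dehydrogenase PRODH, the adenosine receptor ADORA1, the co-stimulatory receptor TNFRSF9 (4-1BB), the mono-ADP-ribosyltransferase PARP10, the tight-junction gene CLDN4 and the alkaline phosphatase ALPG. ZBED6 (-2.85 ± 0.30; chromosome 1, 203795623 to 203854124) and the centrosomal gene ALMS1 (-2.82 ± 0.31; chromosome 2, 73385758 to 73609919) fell most. Falls between -2.56 and -2.29 were found for KIAA1109, CHD9, ZDBF2, TEX15, DICER1, which cleaves microRNA precursors, BRCA2, NKTR and VPS13A. Adjusted p by edgeR's test was between 3.57e-07 for SYT12 and 0.000176 for CLDN4. The 10 falling genes have deposited lengths of 11476 to 19981 nt. Trend-removed, all 20 were still past the threshold in the same direction, with rises of 1.21 (ALPG) to 2.36 (TNFRSF9) and falls of -2.05 (ALMS1) to -1.16 (VPS13A). They were picked as extremes of the same libraries, so this is no independent support. Of 1721 genes with GC content and length that changed at least 2-fold, 1331 also kept their call and direction.

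**Figure D2:**
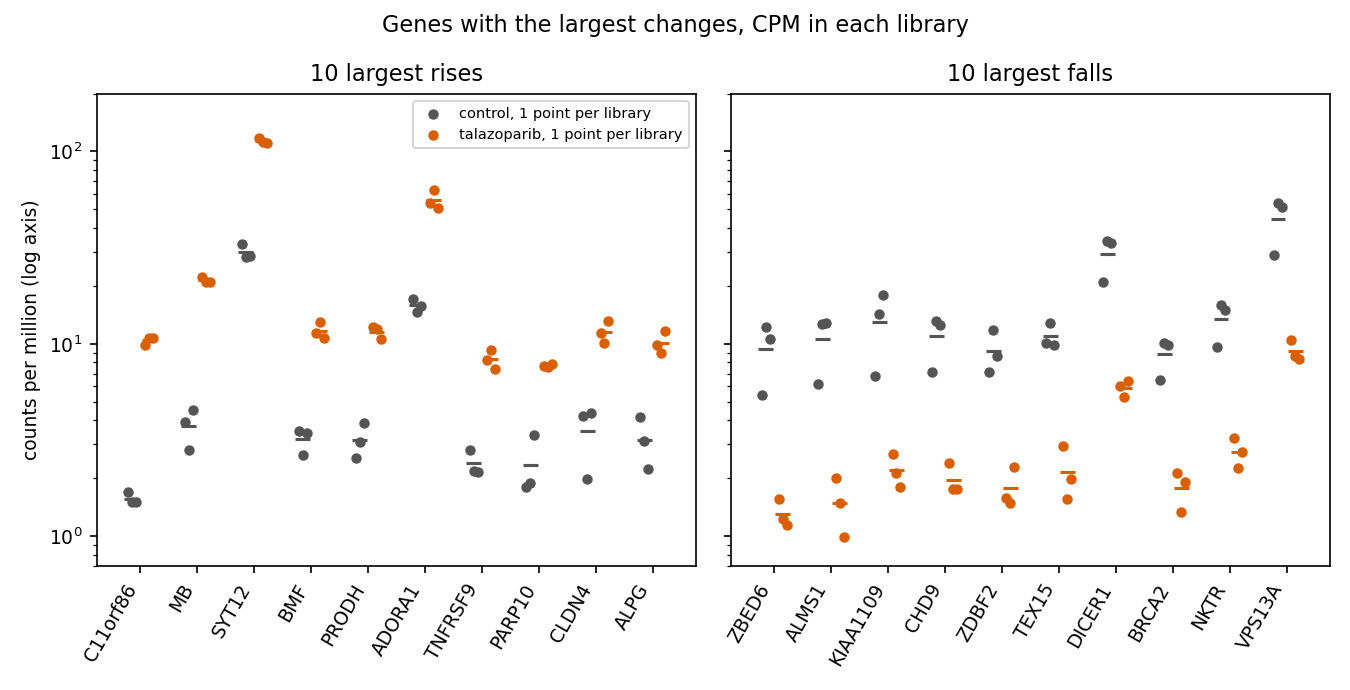
CPM (log axis) of the 10 genes with the largest rises and the 10 with the largest falls under the naming rule; each point is 1 library, and a bar marks the mean of 3 libraries. C11orf86 went from a mean of 1.57 to 10.5 CPM, and the groups do not overlap in any of the 20 genes.

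Of 17 NF-kB targets and inflammatory cytokines tested, 10 rose, 3 fell and 4 did not pass, with a median log2 fold change of 0.90 (camera adjusted p = 0.00665; adjusted p = 0.50 with an estimated correlation). ICAM1 (1.23 ± 0.08 / 0.89), the cytokine LIF (1.14 ± 0.08 / 0.86), the NF-kB inhibitor NFKBIA (1.11 ± 0.09 / 0.78) and CXCL8 (1.45 ± 0.12 / 1.94) rose. IL1B (-1.80 / -1.72), BIRC3 (-0.88 / -0.10) and SOD2 (-0.33 / 0.65), chosen after their values were seen, fell; trend-removed, SOD2 rose and BIRC3 did not pass. Those 3 calls were lost when single libraries were left out: IL1B without control replicate 3 (-1.28), BIRC3 without control replicate 2 (-0.79) or 3 (-0.89), and SOD2 without any of control replicates 1 to 3 or talazoparib replicates 1 and 2 (-0.38 to -0.21). Members of this list had a median of 45.7% GC and 2275 nt; trend-removed, the median was 0.78 with 11 higher and 1 lower (camera adjusted p = 0.000413; 0.23 with an estimated correlation).

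MHC class I antigen presentation genes were higher as a group. Of 17 tested, 13 rose, 1 fell and 3 did not pass (median 0.48, camera adjusted p = 0.00209; adjusted p = 0.50 with an estimated correlation). Of all genes in the GC decile of the list's median, 41.3% rose and 7.87% fell. PSMB8 (1.25 ± 0.11 / 0.83) and PSMB9 (1.38 ± 0.18 / 0.96), subunits of the immunoproteasome, and the class I molecule HLA-E (0.59 ± 0.07 / 0.30) rose. The peptidase ERAP1, chosen after its values were seen, fell (-0.38 / 0.55) and rose trend-removed. Trend-removed, 11 were higher and 1 lower, with a median of 0.30 (camera adjusted p = 0.000460; 0.23 with an estimated correlation). Interferon-stimulated genes showed 9 rises and 3 falls among 19 tested (median 0.41), and camera's adjusted p was 0.0783. IFI6 (1.29 / 0.78), ISG15 (0.95 / 0.26) and IRF7 (0.78 / 0.25) rose and HERC5 fell (-0.94 / -0.58); IRF7 did not pass trend-removed. This list passed camera trend-removed (median 0.40, adjusted p = 0.00574; adjusted p = 0.25 with an estimated correlation) and without control replicate 2 (median 0.51, adjusted p = 0.0261), control replicate 3 (0.46, 0.0247) or talazoparib replicate 3 (0.43, 0.0455); over all camera settings, an estimated correlation included, its adjusted p ran from 0.00225 to 0.501.

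Stress and lysosome genes also shifted upward. In the integrated stress response list, 14 of 20 rose, 2 fell and 4 did not pass (median 0.49, camera adjusted p = 0.00572; adjusted p = 0.51 with an estimated correlation). Genes matched to its members on GC content and length had a typical log2 fold change of 0.236. DDIT4 (0.91 ± 0.09 / 0.44), TRIB3 (0.84 ± 0.09 / 0.43), STC2 (0.62 ± 0.08 / 0.53) and the glutathione-degrading CHAC1 (0.94 ± 0.13 / 0.68) rose. SLC7A11 (-1.04 / -0.09), the cystine transporter, and PSAT1 (-0.21 / 0.16), both chosen here after their values were seen, fell; the call for PSAT1 was lost without talazoparib replicate 1 (-0.21) or 2 (-0.17). Trend-removed, PSAT1 was higher and SLC7A11 did not pass. In that fit 12 members were higher, with a median of 0.21 (camera adjusted p = 0.00139; 0.73 with an estimated correlation). In the lysosome and autophagy list, 12 of 20 rose and 2 fell (median 0.37, camera adjusted p = 0.00485; adjusted p = 0.50 with an estimated correlation). Here the typical value of matched genes was 0.163. The lysosomal enzymes CTSB (0.81 ± 0.08 / 0.71), CTSD (0.81 ± 0.08 / 0.28) and NEU1 (0.80 ± 0.09 / 0.51) rose, while LAMP2 (-0.40 / 0.52) and MAP1LC3B (-0.29 / -0.35), chosen after their values were seen, fell. The trend-removed median of this list was 0.21 (camera adjusted p = 0.0101; 0.63 with an estimated correlation).

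**Figure D3:**
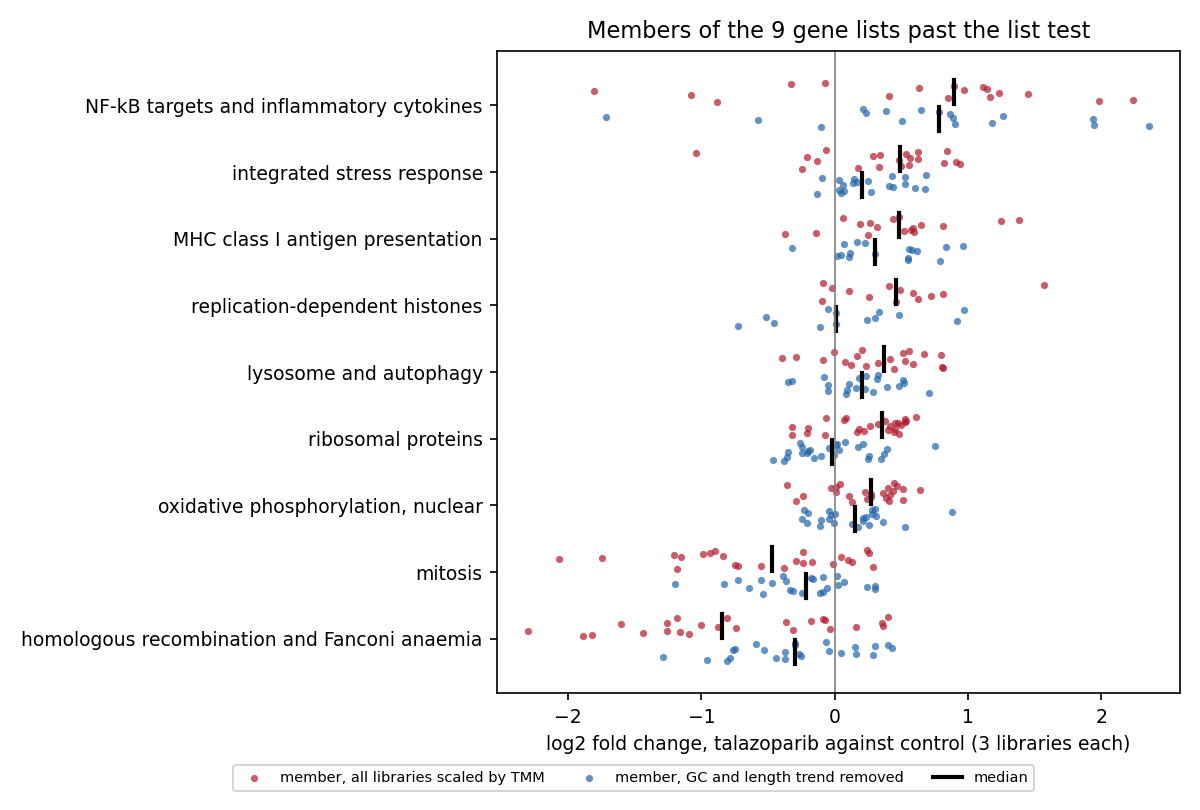
Log2 fold change of every tested member of the 9 gene lists past the list test, from counts scaled by TMM (upper points of each row) and with the GC and length trend removed (lower points); black bars mark medians. The median of the NF-kB list goes from 0.90 to 0.78 with the trend removed, while that of the ribosomal proteins goes from 0.35 to -0.02.

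Mitotic genes were lower as a group: 15 of 24 fell, 3 rose and 6 did not pass, with a median log2 fold change of -0.47 (camera adjusted p = 0.0114; adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone, 16 fell. Of all genes in the GC decile of the list's median, 61.7% fell and 4.15% rose. The kinetochore genes CENPE (-2.07 ± 0.19 / -1.20) and CENPF (-1.75 ± 0.16 / -0.83) and the cytokinesis genes ANLN (-1.19 ± 0.12 / -0.54) and KIF23 (-0.84 ± 0.09 / -0.36) fell, while the mitotic kinases PLK1 (0.26 / -0.16) and AURKB (0.29 / -0.11) and the ubiquitin-conjugating enzyme UBE2C (0.24 / 0.02), chosen after their values were seen, rose. Leaving out control replicate 2 or 3 or talazoparib replicate 1 or 2 ended all 3 of those rises (log2 fold changes of 0.17 to 0.29). Trend-removed, PLK1 was lower, and AURKB and UBE2C did not pass. Members had a median of 43.2% GC and 3303 nt; trend-removed, 12 were lower and 3 higher (median -0.21, camera adjusted p = 0.0222; 0.73 with an estimated correlation). With GC alone removed the list did not pass (median -0.16, camera adjusted p = 0.326).

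Homologous recombination and Fanconi anaemia genes had the lowest list median, -0.84, with 16 of 24 lower, 3 higher and 5 not past the test (camera adjusted p = 0.00485; adjusted p = 0.50 with an estimated correlation). BRCA2 (-2.30 ± 0.23 / -1.29), the DNA damage kinase ATM (-1.89 ± 0.19 / -0.81) and the Fanconi pair FANCI (-1.01 ± 0.11 / -0.53) and FANCD2 (-0.88 ± 0.10 / -0.38) fell. XRCC3 (0.40 / -0.06) and FANCG (0.36 / -0.04), chosen after their values were seen, rose and did not pass trend-removed. With 42.3% GC and 5082 nt in the median, this list had 14 lower members trend-removed, against 4 higher, and its median was -0.30 (camera adjusted p = 0.0290, or 0.73 with an estimated correlation). Of all genes in the GC decile of the list's median, 61.7% fell and 4.15% rose without trend removal. DNA replication genes went both ways, with 8 of 25 higher and 11 lower (median -0.04, camera adjusted p = 0.498); MCM10 (-1.07 / -0.62) and POLE2 (-1.03 / -0.75) fell. Among PARP inhibitor response factors, 2 of 14 rose and 7 fell (median -0.30, camera adjusted p = 0.364), with falls in RIF1 (-2.15 / -1.09), EZH2 (-0.58 / -0.12) and SLFN11 (-0.58 / -0.12). EZH2 and SLFN11 did not pass trend-removed.

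PARP1, a target of the drug, stood at 408 ± 3.01 CPM in controls and 389 ± 22.4 CPM with talazoparib (edgeR adjusted p = 0.435), though it passed as lower under total count scaling (-0.14) and on FPKM values (-0.14). PARP2 fell by 0.26 on the log2 scale (edgeR adjusted p = 0.0190), a call lost without talazoparib replicate 1 (-0.25) or 3 (-0.22) and trend-removed (-0.07). In the list of PARP enzymes and single-strand break repair, 6 of 18 rose and 5 fell, or 6 and 6 adjusted over the list alone (median 0.10, camera adjusted p = 0.772). PARG, which removes ADP-ribose chains, fell (-0.84 / -0.37) and ADPRS rose (0.39 / -0.10), the latter not past the test trend-removed.

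Other fixed groups moved in both directions. In the list of CDKN1A, MDM2 and other genes induced by DNA damage, 10 of 23 rose and 5 fell (median 0.26, camera adjusted p = 0.223), with SESN2 (1.09 / 0.71) and CDKN1A (0.61 / 0.24) higher and ZMAT3 (-1.21 / -0.31) and MDM2 (-1.16 / -0.26) lower. Apoptosis regulators showed 6 rises and 6 falls among 22 (median 0.04, camera adjusted p = 0.683), led by BMF (1.87 / 1.69) and the inhibitor of apoptosis BIRC2 (-1.35 / -0.72). Epithelial junction and keratin genes rose in 6 and fell in 5 of 15, or 6 adjusted over the list alone (median 0.13, camera adjusted p = 0.451); the plakoglobin gene JUP (1.18 / 0.80) and KRT19 (1.13 / 0.56) rose. Of 14 mesenchymal and matrix genes, 5 rose and 5 fell (median 0.05, camera adjusted p = 0.830), including ITGA5 (0.60 / 0.28) and THBS1 (-0.58 / -0.10), whose call ended trend-removed. In hypoxia and glycolysis, 8 of 19 rose and 5 fell (median 0.16, camera adjusted p = 0.543), with hexokinase HK2 (53.6 ± 2.82 to 26.8 ± 1.69 CPM) and ADM (-1.14 / -1.63) lower. Cholesterol synthesis genes rose in 6 and fell in 8 of 20, or 7 and 8 adjusted over the list alone (median 0.01, camera adjusted p = 0.772), with HMGCS1 (-1.19 / -0.45) and SC5D (-1.07 / -0.27) lower. Endoplasmic reticulum chaperones rose in 7 and fell in 7 of 18, or 8 and 7 adjusted over the list alone (median 0.11, camera adjusted p = 0.709), CALR at 0.57 / 0.24 and DNAJB11 at -0.42 / -0.58. NRF2 targets rose in 11 and fell in 4 of 18 (median 0.35, camera adjusted p = 0.0636), and the list passed without control replicate 1 (median 0.38, adjusted p = 0.0400) or 2 (0.28, 0.0486). Over all camera settings its adjusted p ran from 0.00430 to 0.77, the latter trend-removed with an estimated correlation. The exporter ABCC3 rose (0.94 / 0.79) and SLC7A11 fell (-1.04 / -0.09). Immediate-early and MAPK output genes rose in 6 and fell in 1 (MYC, -0.22 / -0.39, chosen after its values were seen and not past the test without talazoparib replicate 1, -0.20) of 18 (median 0.08, camera adjusted p = 0.223), with IER3 (0.69 / 0.16) and JUNB (0.75 / 0.20) higher. With the GC and length trend removed, no list of this paragraph passed camera (NRF2 targets: median 0.17, adjusted p = 0.0711); the NRF2 list passed with GC alone removed (median 0.30, adjusted p = 0.00430) and with the GC by length surface removed (0.19, 0.0211).

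Genes with short or GC-rich mRNAs for energy, ribosomes and chromatin were higher. Their list calls ended with the GC and length trend removed and held with GC alone removed: medians 0.31, 0.18 and 0.36 for oxidative phosphorylation, ribosomal proteins and histones (camera adjusted p = 0.000184, 0.0446 and 0.0381). They also ended with length alone removed (camera adjusted p = 0.989, 0.989 and 0.755), with the GC by length surface removed (0.202, 0.896 and 0.608) and, in the fit without trend removal, with an estimated correlation (0.63, 0.71 and 0.50). NDUFS8 and RPS9 did not pass trend-removed. Nuclear oxidative phosphorylation genes rose in 14 and fell in 3 of 24, or 15 and 3 adjusted over the list alone (median 0.27, camera adjusted p = 0.0157; adjusted p = 0.63 with an estimated correlation), with NDUFS8 (0.64 / -0.02) and COX4I1 (0.51 / 0.26). Trend-removed, the median was 0.15 and camera's adjusted p 0.325. Ribosomal protein genes rose in 16 and fell in 3 of 26, or 16 and 4 adjusted over the list alone (median 0.35, camera adjusted p = 0.0114; adjusted p = 0.71 with an estimated correlation), with RPS9 (0.61 / 0.08) and RPS19 (0.53 / 0.17). Trend-removed, 8 rose and 11 fell (median -0.02, camera adjusted p = 0.551). Replication-dependent histone genes rose in 7 of 13 (median 0.46, camera adjusted p = 0.0114; adjusted p = 0.50 with an estimated correlation), with H2AC6 (0.72 / 0.92) and H2BC21 (0.49 / 0.48). Trend-removed, the median was 0.01 and camera's adjusted p 0.669. Mitochondrially encoded genes took 10.2%, 9.82% and 9.82% of all counts in the control libraries and 9.21%, 8.11% and 9.16% in the talazoparib libraries, lower in each of the 3. Of 13 tested, ND3 (0.47) rose and ND4 (-0.35), ND4L (-0.35) and ND5 (-0.39) fell (list median -0.05, camera adjusted p = 0.683; without talazoparib replicate 2 the list's direction turned, with a median of 0.001).

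Among 7 luminal prostate genes tested, 3 fell, FKBP5 (-0.57 / 0.29) and STEAP2 (-1.18 / -0.19) among them. Trend-removed, FKBP5 was higher and STEAP2 did not pass. The list's median was -0.11 (camera adjusted p = 0.389). Of 3 neuroendocrine genes tested, ENO2 rose (0.41 / 0.07), with a list median of 0.27 (camera adjusted p = 0.239); trend-removed, ENO2 did not pass and the list's median was -0.20. CTNNA1 was detected at 302 ± 5.26 CPM in controls and did not pass (0.04 / 0.23), its sign turned under total count scaling (-0.04), and it passed as higher trend-removed. Among fibroblast, endothelial and leukocyte markers, PTPRC, CD3E, DCN and COL1A2 had no counts and LYZ reached 0.0505 CPM. Of the 4 tested, CD68, a lysosomal glycoprotein also used as a macrophage marker, rose (1.35 / 0.95, from 25.9 ± 1.76 to 66.2 ± 4.52 CPM), CD14 rose (1.02 / 0.55, to 1.86 ± 0.374 CPM; not past the test trend-removed) and COL3A1 fell (-0.40 / -0.43), the last a call lost without control replicate 2 or 3 or talazoparib replicate 1 or 2 (-0.44 to -0.32); the list's median was 0.51 (camera adjusted p = 0.389).

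By camera, 9 of the 26 lists shifted, 7 upward and 2 downward. With an estimated correlation camera called 0 lists, with 2 at an unadjusted p under 0.05, and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, called 19. The estimated correlations of the NF-kB, mitosis and histone lists (0.0186, 0.0261 and 0.0121) lay near the preset 0.01. Those of the other shifted lists ran from 0.153 to 0.819. The loss of every call thus does not rest on correlation between genes alone. Adjusted over the list alone, the member counts of 19 lists equalled those over all genes tested, and the other 7 are given above. In 6 lists (PARP enzymes, apoptosis regulators, endoplasmic reticulum chaperones, cholesterol synthesis, mesenchymal genes, and hypoxia and glycolysis) the median, mean and test differed in sign, and none of the 6 passed camera.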

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

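Removal of the GC and length trend, in each of its forms, was chosen after the data were examined; the other settings were fixed before. The number of changed genes was within 1.5 times the reported 8200 under every scaling, filter and test tried except the fold thresholds, which call fewer genes by construction: glmTreat at 1.5-fold gave 1805 genes (343 higher, 1462 lower), and an absolute log2 fold change of at least 1 gave 1807 (398 higher, 1409 lower). Leaving out 1 library at a time gave 6353 to 8549 changed genes, 2622 to 3973 higher and 3731 to 4576 lower, and 9 to 11 lists. The 9 shifted lists became 0 with an estimated correlation and 19 with fry, which tests another null hypothesis. Trend removal in its different forms gave 5764 to 7337 changed genes. At this depth 3 counts in a library correspond to 0.0758 to 0.0767 CPM, and levels under that are not told from 0. Among the named genes IL1B had the widest error (log2 fold change -1.80 ± 0.48), with 1.65, 1.26 and 3.52 CPM in the controls.

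The fit with the replicate number as a block gave 7580 changed genes (3419 higher, 4161 lower). Of the named genes, PSAT1 (-0.21) and MYC (-0.22) lost their calls there, and no list call changed. The numbers gave no sign of pairing: deviations of same-numbered libraries correlated at -0.094, -0.173 and 0.004, and no control library correlated best with its own number. With 3 libraries per group this does not exclude that same-numbered libraries shared a culture or day.

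Among the named genes, leaving out 1 library ended 29 calls over the 6 settings and added 1; the genes and libraries are given beside their values. For lists it added 5 calls and ended none. CTNNA1, which did not pass, changed sign without control replicate 2 (-0.005; up to 0.066 without talazoparib replicate 3), under total count scaling (-0.035) and on FPKM values (-0.034 with a pseudocount of 1, with or without a filter, and -0.035 with 0.1). The list of mitochondrially encoded genes changed direction without talazoparib replicate 2 (median 0.001). On FPKM values the histone list lost its call (adjusted p = 0.0524), and on ranks the NRF2 list gained one (adjusted p = 0.0468); over all camera settings the histone list's adjusted p ran from 0.00499 to 0.809. PARP1 and KDM2A gained calls under total count scaling and in 3 fits to FPKM values, and KDM2A also with a mean CPM of at least 5 (-0.18). The cause was not tested for any of these.

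Trend removal turned directions because its offset moves genes by their GC content and length. With GC and length removed, log2 fold changes of the opposite sign were PLK1 -0.16, AURKB -0.11, XRCC3 -0.062, FANCG -0.039, SOD2 0.65, ERAP1 0.55, PSAT1 0.16, LAMP2 0.52, NDUFS8 -0.024, ADPRS -0.098, FKBP5 0.29 and KDM2A 0.003; list medians where the direction of the test turned were PARP enzymes and single-strand break repair -0.068, mesenchymal and extracellular matrix genes -0.18, hypoxia and glycolysis -0.006, ribosomal proteins -0.024, immediate-early and MAPK output genes 0.10 and neuroendocrine genes -0.20. With GC alone they were PARP2 0.081, PLK1 -0.057, XRCC3 -0.026, SOD2 0.27, ERAP1 0.34, PSAT1 0.36, LAMP2 0.35 and FKBP5 0.051, and mesenchymal and extracellular matrix genes -0.20, hypoxia and glycolysis -0.089 and neuroendocrine genes -0.12. With length alone they were UBE2C -0.055, SOD2 0.42, ERAP1 0.18, LAMP2 0.12, FKBP5 0.006 and KDM2A 0.31, and PARP enzymes and single-strand break repair -0.003, endoplasmic reticulum chaperones 0.007 and ribosomal proteins 0.085. With the GC by length surface they were PLK1 -0.13, AURKB -0.078, XRCC3 -0.039, FANCG -0.016, SOD2 0.66, ERAP1 0.57, PSAT1 0.11, LAMP2 0.56, ADPRS -0.034 and FKBP5 0.32, and PARP enzymes and single-strand break repair -0.055, mesenchymal and extracellular matrix genes -0.17, hypoxia and glycolysis -0.041, ribosomal proteins 0.019 and neuroendocrine genes -0.17. With GC and length removed and control replicate 1 left out they were PLK1 -0.14, AURKB -0.074, XRCC3 -0.062, FANCG -0.017, SOD2 0.75, ERAP1 0.65, PSAT1 0.21, LAMP2 0.58, ADPRS -0.073, FKBP5 0.34 and KDM2A 0.017, and PARP enzymes and single-strand break repair -0.061, mesenchymal and extracellular matrix genes -0.15, hypoxia and glycolysis 0.069, ribosomal proteins 0.001 and neuroendocrine genes -0.20. Camera's adjusted p for the mitosis list was 0.326 with GC alone removed, 0.0222 with GC and length, 0.0211 with the surface and 0.0002 with length alone. A further 55 gene calls and 9 list calls ended in these 5 settings, and 6 and 6 were added.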

Other observations

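The gene groups in this paragraph lie outside the fixed lists and were chosen after their values were seen, and no list test was run on them. Of 13 MHC class II pathway genes, 8 were tested, while HLA-DRA, HLA-DPB1, HLA-DQA1, HLA-DOA and CIITA did not pass the count filter. The 8 had control means of at most 19.1 CPM (IFI30), and all were higher with talazoparib, with a median log2 fold change of 1.39 (6 of 8 trend-removed, median 0.99). CTSS, CD74 and HLA-DPA1 stood at only 0.0745, 0.167 and 0.289 CPM in controls. HLA-DMA, which loads peptides onto class II molecules, went from 7.56 ± 1.12 to 20.0 ± 0.500 CPM (SD, n = 3 each) and HLA-DRB1 from 7.67 ± 0.522 to 18.2 ± 1.54 CPM. Ligands of the NKG2D receptor of natural killer cells split, with 3 of 7 higher and 1 lower (median 0.22; 3 higher and 2 lower trend-removed, median 0.11); RAET1E (1.60 ± 0.15, SE; 1.99 trend-removed) and RAET1G (1.72 ± 0.19; 1.37) had the largest rises. Of 12 YAP target genes 9 fell (median -0.59), among them ANKRD1 (-0.83 ± 0.10, and -0.54 trend-removed) and CCN2 (-0.45 ± 0.08, and -0.64). Trend-removed 9 also fell (median -0.42), but THBS1 and F3 lost their calls while CCN1 and AXL gained them. Of all genes tested, 29.9% fell without trend removal. The secreted factors IL11 (-1.63 ± 0.11; -1.97 trend-removed) and IGFBP3 (-2.04 ± 0.22; -2.10) fell, and TXNIP, an inhibitor of thioredoxin, rose (1.61 ± 0.14; 1.95). Adjusted p by edgeR's test for the genes given here with an error was between 2.88e-06 for IL11 and 0.000366 for CCN2.

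C11orf86 and SYT12, both among the 10 largest rises, are neighbours on chromosome 11 of GRCh38, SYT12 lying from 67006771 to 67050863. The genes on either side were also higher: PC, which encodes pyruvate carboxylase (0.86 ± 0.08; 0.64 trend-removed; 66848420 to 66958383), and RHOD (1.09 ± 0.11; 0.47; 67056847 to 67072017), both named after their values were seen. The next gene, KDM2A, also named after its values were seen, did not pass (-0.14 ± 0.07, adjusted p = 0.0973 by edgeR's test); without control replicate 1 it passed as lower (-0.19). Whether neighbouring genes rise together more often than by chance was not tested.

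In the weighing of explanations that follows, the tests were chosen after the results were seen, except the counts over other splits of the libraries. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Every other split has libraries of both groups on each side, so any difference between the groups adds to the spread there and lowers its counts. The real split, 1 of the 10, gave 8200 changed genes and the highest other split 0 by edgeR (380 at an unadjusted p under 0.05). With the GC and length trend removed, the counts were 6063 and 0 (341 unadjusted), again with 1 split as high as the real one. For lists the real split gave 9 by camera and the highest other 5, so 1 of 10 splits reached 9.

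Long AT-rich mRNAs were lower with talazoparib: log2 fold change correlated across genes, which are not independent replicates, with GC content (Spearman 0.687) and with mRNA length (-0.455). The length of the transcribed gene, as in a defect of elongation along long genes, is argued against. With GC content and deposited length held fixed, the slope was -0.0023 ± 0.0030 (SE) per doubling of genomic span. It was -0.169 per doubling of deposited length. A candidate explanation is a difference between RNA samples or libraries that arises without the drug: with no library on both sides, where independent noise gives 0, control replicate 1 against 2 correlated across genes at 0.574 with the talazoparib libraries against control replicate 3, and control replicate 1 against 3 at 0.525 with them against control replicate 2. Control replicate 2 against 3 gave -0.171, and pairs of talazoparib libraries -0.306, 0.193 and 0.390. A response of such mRNAs to the drug cannot be told apart from it, because every control library has a negative and every talazoparib library a positive GC slope; the smallest gap between libraries of different groups was 0.225 log2 units per 10 points of GC, and the largest within a group 0.227.

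NF-kB targets and MHC class I genes were higher. For the NF-kB list the GC and length trend as the whole cause is argued against. With it removed the NF-kB and MHC class I medians were 0.782 and 0.304, and camera's adjusted p was 0.000413 and 0.00046 (0.000186 and 0.000168 with the GC by length surface removed). Among 10000 random lists of genes drawn one by one and matched on GC content and length, the NF-kB median of 0.896 stood above 100% and the MHC class I median of 0.479 above 99.72%. Genes in the matched bins had typical values of 0.064 and 0.315. RNA from leukocytes, which also express these genes, is argued against by PTPRC, CD3E and LYZ, whose highest level in any library was 0.0505 CPM, though CD68 and CD14 rose (CD14 not past the test trend-removed). A hypothesis that stays open is an inflammatory and antigen presentation response of the DU 145 cells to the drug. Neither list passed camera with an estimated correlation (adjusted p = 0.50 for both, 0.23 for both trend-removed). That test has little power with 6 libraries, so its result does not decide the question. The estimated correlation was 0.0186 for the NF-kB list and 0.22 for the MHC class I list.

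Mitosis genes and homologous recombination genes were lower, and both lists are AT-rich. For mitosis the GC and length trend may be the whole cause: the median was -0.468 (quartiles -0.946 and 0.003), -0.164 with GC alone removed (quartiles -0.415 and 0.155), where camera's call ended (adjusted p = 0.326), and -0.213 with GC and length removed (quartiles -0.491 and -0.041), where it passed (adjusted p = 0.0222). With the GC by length surface removed it also passed (-0.181, adjusted p = 0.0211), so the tables leave it open, and why GC alone ended the call was not tested. Of the 10000 matched random lists, 4.75% lay below the list's median, where genes in the matched bins had a typical value of -0.375. For homologous recombination and Fanconi anaemia the median went from -0.844 (quartiles -1.256 and -0.083) to -0.300 with GC alone removed (quartiles -0.593 and 0.051) and -0.296 with GC and length removed (quartiles -0.627 and 0.072), so some members lie above 0. Camera's adjusted p stayed past its threshold (0.0286 with GC alone, 0.029 with both, 0.0211 with the surface), and 0.28% of matched random lists lay below its median (typical value -0.502 in the matched bins), which argues against the trend as the whole cause though it may account for the larger part. Lower expression of this repair group in response to the drug is a hypothesis that stays open. Neither the mitosis list nor this one passed camera with an estimated correlation (adjusted p = 0.73 for both, trend-removed). That test has little power with 6 libraries, so its result does not decide the question.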
